A study of Mus musculus with 6 samples.

How the data were processed

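Expression was measured with the Affymetrix Mouse430_2 array in 3 leukemia and 3 wild-type samples of sorted Lin-/Sca1-/cKit+ cells, from 200 ng of total RNA each with biotin-labelled cRNA, per the labels. Groups and replicate numbers were taken from the sample titles. The leukemia samples name numbered mice, while the wild-type samples name mice in the plural, so pooling of animals is not excluded and the p-values measure only the spread between these samples. The deposited values are intensity values on a linear scale, and per the submitters' processing notes RMA was used, whose version is not given in the sources used here. Which background correction, normalization and scaling were applied is likewise not given there beyond that name. RMA usually gives log2 values, and log2 values had been assumed when the test was chosen. The table held linear values from 3.31 to 18869, so log2 was taken with no pseudocount and the same limma test was kept. The array run records deposited for each sample served only to find the fluidics run and chip lot of each array (2 runs, 1 lot). The lot was read from the file headers, and arrays with the same hybridization date entry there were taken as 1 fluidics run. All 6 value columns were mapped to samples, leaving 0 columns not mapped.

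The deposited table held 28821 probe sets, and every percentile of all probe sets given here is taken over these. Of these, 23750 had 1 gene symbol in the platform annotation, 677 had several, 4355 had none and 39 were controls. Only probe sets with 1 symbol were named. The gene ID of 23674 of them matched the RefSeq gene table of GRCm38.p6, which changed 0 symbols and was used for names only, so no coordinates are given. Of several probe sets of a gene the one with the highest mean over the 6 arrays was used. This gave 13146 genes, of which 9715 lay at or above their array's 40th percentile of all probe sets on at least 3 arrays and were tested, while 3431 were left out as dim. Of the genes at least 2-fold lower in leukemia, 474 lay below that percentile on all leukemia arrays, and of those at least 2-fold higher, 196 lay below it on all wild-type arrays. No detection calls were used. Among changed genes with a further tested probe set (1678), 40 had one that changed in the opposite direction, Mycn among them.

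Leukemia was compared with wild-type with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, 4 residual degrees of freedom, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05), with no covariate. Changes are leukemia minus wild-type on the log2 scale. Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 23 tested lists, with an estimated correlation and fry as alternatives. With the preset correlation 12 lists passed (4 higher, 8 lower), and with an estimated correlation 0 passed, 4 of them at an unadjusted p under 0.05. Of the fry tests, which do not set a list against other genes, 14 lists passed in a direction and 23 in either direction. The design, the 24 lists, the named-gene rule and the alternatives were fixed before the data were examined, except log2(value + 16) and fry, chosen after seeing the data. Named genes were the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap (sex-linked genes aside), up to 2 members per direction of each list, and a panel of 16 regulators and sort markers, of which 15 were measured. Ly6a, the gene of the sort marker Sca1, has no named probe set in the deposited table.

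Alternatives covered the filter on dim genes, the rule for probe sets, centring and quantile normalization, the moderation of the variance, array weights, the replicate number and the fluidics run as blocks, and leaving out each array. The procedure was tested on simulated data of 9715 genes, with 200 genes changed in the comparison of leukemia with wild-type. Genes were drawn independently, each with 1 spread for both groups, taken from the fit to these arrays. The procedure recovered 10.4% of genes changed by 0.5, 67.2% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale. It made 6 false calls, and 0 calls when no gene was changed. In the real arrays the median SD was 0.22 in leukemia against 0.11 in wild-type, and 42.1% of tested genes passed. Genes of some lists were also correlated, so these rates need not hold for the real data. Single values were compared with exact permutation tests, two-sided. Left out of the gene comparison were control probe sets and probe sets with no or several symbols. Figures were drawn with matplotlib 3.10.9.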

Results

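Gene expression was measured in sorted Lin-/Sca1-/cKit+ cells of mice, the marrow fraction that holds committed myeloid progenitors and that lacks lineage markers and Sca1 but carries the receptor Kit. In 3 samples the cells came from the spleens of mice with leukemia driven by AE9a, a truncated AML1-ETO fusion protein that had been introduced into transplanted progenitors, and in 3 samples from the bone marrow of wild-type mice. All were of the MF1 strain and 12 to 16 weeks old. Each sample was hybridised to 1 Affymetrix array from 200 ng of total RNA, and 6 arrays limit the precision of every value. The median deposited intensity per array ran from 71.6 to 79.9. The series name puts the question as how a leukemia fraction enriched for initiating cells differs from its normal counterpart.

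The arrays of the groups stood apart. Pearson's r over all probe sets was 0.992 to 0.994 within the wild-type arrays, 0.969 to 0.978 within the leukemia arrays and 0.902 to 0.925 between the groups. Leukemia replicates varied more, with a median SD per gene of 0.22 against 0.11 on the log2 scale. Leukemia replicate 1 stood apart from the other leukemia arrays. It correlated with them at 0.969 and 0.970, against 0.978 between those, lay at -61.5 on the second principal component against 26.4 and 37.2, and had an array weight of 0.191 against 0.831 to 2.82 for the other 5 arrays. It was also the only leukemia array in the fluidics run of the wild-type arrays, by its hybridization date entry. With the run as a block, each change is therefore that of leukemia replicate 1 alone against the wild-type mean, and its p assumes that this array varies like the others. Some measures outside the gene groups differed between the groups or among the leukemia arrays. The 5' probe set for 18S ribosomal RNA, a transcript that poly(A) priming should largely leave out, was 8.73-fold higher on the leukemia arrays (11.58 ± 0.67 against 8.45 ± 0.85 log2, SD, n = 3 each, exact permutation p = 0.1, two-sided, the smallest p that 3 against 3 allows). The 3' minus 5' difference of Gapdh was 0.23 higher on the log2 scale in leukemia (exact permutation p = 0.1), and that of Actb differed by 0.03 (exact permutation p = 0.9). Both were highest on leukemia replicate 1, as was the 18S value, and without that array the differences were 0.14 for Gapdh and -0.10 for Actb, while Actb was at -0.03 without wild-type replicate 1. The Y-linked Eif2s3y was at 8.12 to 8.22 log2 on the wild-type arrays and at 3.02, 8.46 and 9.05 on leukemia arrays 1, 2 and 3, and Xist, transcribed from the inactive X chromosome, was at 4.23 to 4.73 on the wild-type arrays and at 11.02, 9.41 and 5.03 on the leukemia arrays. The 18S and Gapdh differences accompany each gene group described here.

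Most genes of granulocyte and monocyte progenitors were lower in the leukemia cells, led by Mpo, Plac8 and Ctsg. The enzymes Tph1 and Ddc, the signalling inhibitor Socs2 and the mast cell and basophil receptor Cd200r3 were among the genes that were higher. Of 9715 genes tested, 4089 changed (limma, adjusted p under 0.05), 1637 higher and 2452 lower in leukemia. A change of at least 2-fold was found for 1849 of them, 725 higher and 1124 lower, and a change of at least 16-fold for 187, 53 higher and 134 lower. The groups did not overlap for 4083 of the 4089 changed genes. Over all tested genes 59.2% did not overlap, where chance gives 10%. Without wild-type replicate 3 the count of changed genes was 2647. Without leukemia replicate 1 it was 4716, with 1836 of at least 2-fold.

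The largest rise was that of Tph1, the rate-limiting enzyme of serotonin synthesis, from 3.30 ± 0.18 to 11.43 ± 1.37 log2 (SD, n = 3 each; change 8.14 ± 0.62 SE, limma adjusted p = 1.02e-04). Ddc, the decarboxylase that carries out the next step of that pathway, rose by 7.85. The cardiac troponin Tnni3 rose by 7.13, the myelin protein gene Pmp22 by 7.03, 1700042O10Rik by 6.58, the deiminase Padi3 by 6.07 and the collectin Colec11 by 6.03. Mycn, a MYC family transcription factor, rose by 5.88 with its brightest probe set, but another tested probe set of the same gene fell by 3.66, so its direction depends on the probe set. The largest fall was that of Mpo, the myeloperoxidase of primary granules, from 13.43 ± 0.09 to 4.12 ± 0.12 (change -9.31 ± 0.12 SE, limma adjusted p = 1.40e-07). Plac8 fell by 8.61, the granule proteases Ctsg and Elane fell by 7.81 and 7.66, Ptprc, which encodes the pan-leukocyte antigen CD45, fell by 7.64, the chemokine Ccl9 fell by 7.30, Ifitm1 fell by 7.20 and BC035044 fell by 7.07. The 8 risen genes lay below the 40th percentile of all probe sets on every wild-type array, and 7 of the 8 fallen genes below it on every leukemia array, so that the sizes depend on the handling of background. Without leukemia replicate 2 the change of Tph1 was 7.41 and that of Ctsg -8.57, and without leukemia replicate 3 that of Tph1 was 8.78. With 16 added before the log the rises were 4.52 to 6.75 and the falls -8.37 to -6.04.

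**Figure D1:**
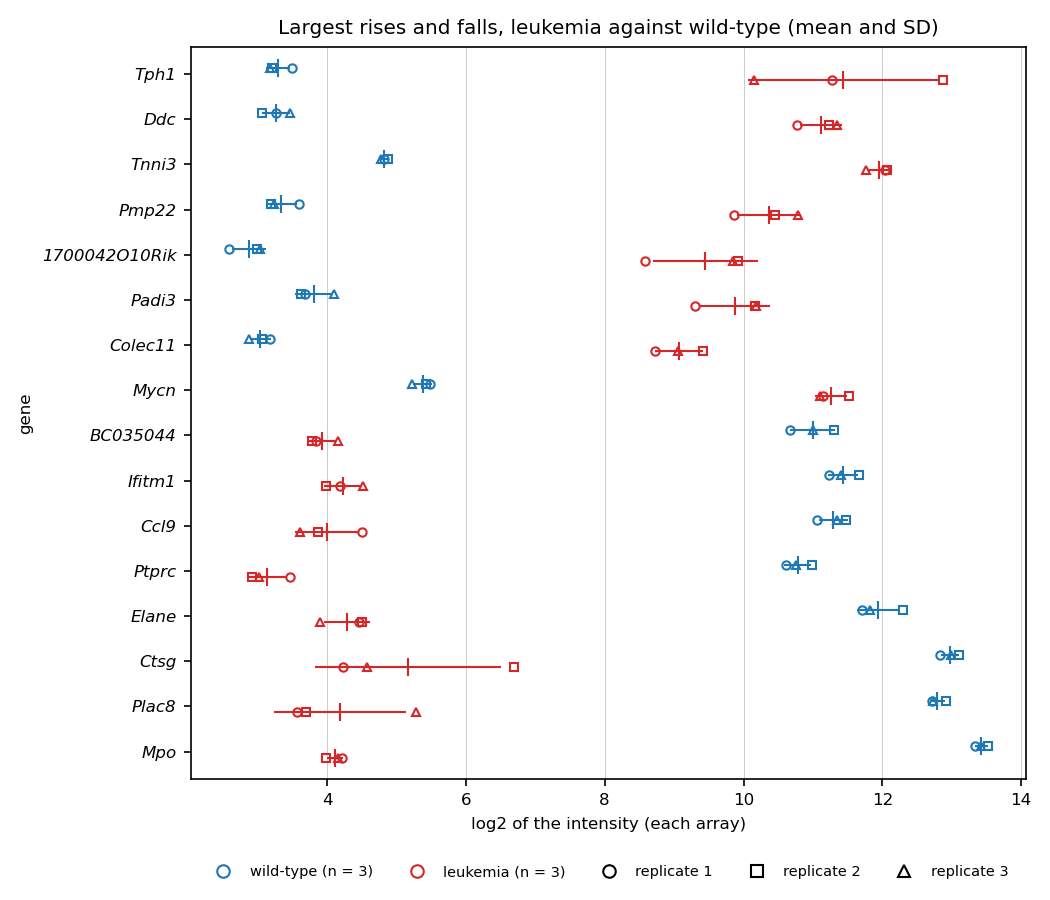
Log2 intensity (horizontal axis) of the 8 genes with the largest rises and the 8 with the largest falls (vertical axis), blue for wild-type and red for leukemia arrays, marker shape for the replicate, and a vertical tick with a bar for the mean and SD of 3 arrays. Only genes whose groups did not overlap could be chosen, so by that rule no leukemia value lies within the wild-type range. The changes run from 8.14 for Tph1 to -9.31 for Mpo.

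Genes of granulocyte and monocyte progenitors fell together. Of 18 tested primary granule and GMP (granulocyte-monocyte progenitor) genes 16 fell and 0 rose, also adjusted over the list alone, and the median change was -5.02 (limma's camera, adjusted p = 3.91e-09; adjusted p = 0.240 with an estimated correlation). Among them were Mpo and Plac8. Of 18 monocyte and macrophage genes 14 fell and 0 rose (15 fell adjusted over the list alone), with a median of -3.30 (camera adjusted p = 1.05e-08; adjusted p = 0.240 with an estimated correlation). The transcription factor Irf8 fell by 6.87 and Ly86 fell by 6.50. Of the 5 tested secondary granule and mature neutrophil genes 4 fell, also adjusted over the list alone, with a median of -4.11 (camera adjusted p = 0.00198; adjusted p = 0.247 with an estimated correlation), led by Mgst1 (fell by 6.24) and Anxa1 (fell by 5.92). Of 10 MHC class II presentation genes 8 fell and 1 rose, also adjusted over the list alone, with a median of -3.50 (camera adjusted p = 0.00110; adjusted p = 0.240 with an estimated correlation). H2-Aa, an MHC class II chain, fell by 6.46 and H2-DMa fell by 4.99, while the lysosomal reductase Ifi30 rose by 0.78. With the fluidics run as a block the medians of these 4 lists were -5.05, -3.37, -3.96 and -3.53. Without the filter on dim genes the median was -1.74 for the monocyte and -1.14 for the secondary granule list, and the MHC class II call was lost with probe sets free of shared endings (camera adjusted p = 0.112).

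The erythroid list, the megakaryocyte list and the list of mast cell, basophil and eosinophil genes each held members that rose and members that fell. Of 26 erythroid and MEP (megakaryocyte-erythroid progenitor) genes 11 rose and 3 fell, also adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.0132; adjusted p = 0.694 with an estimated correlation). Alas2, the erythroid enzyme that starts heme synthesis, rose by 3.87 and Slc4a1, which encodes the red cell anion exchanger, rose by 3.16, while the water channel gene Aqp1 fell by 6.89 and Add2 fell by 2.37. Aqp1 was spread over the leukemia arrays (3.06, 4.43 and 7.75 log2, SD 2.42), and its change was -5.88 without leukemia replicate 1, -8.23 without leukemia replicate 3 and -8.92 with the block. The call of this list was lost without wild-type replicate 2 (median 0.19, camera adjusted p = 0.0541), without leukemia replicate 3 (camera adjusted p = 0.0748) and with the fluidics run as a block (median 0.26, camera adjusted p = 0.280). Of 12 megakaryocyte and platelet genes 3 rose and 7 fell, also adjusted over the list alone, with a median of -1.51 that did not pass (camera adjusted p = 0.118, median -1.46 with the block and -0.62 without the filter on dim genes). Cd9 fell by 4.90 and Pf4, platelet factor 4, fell by 3.85, whereas the platelet glycoprotein gene Gp5 rose by 2.05 (1.07 with the block) and Rab27b rose by 1.73. Of 13 mast cell, basophil and eosinophil genes 7 rose and 4 fell, also adjusted over the list alone, and the list did not pass (median 0.26, camera adjusted p = 0.197, median 0.28 with the block). Cd200r3, a receptor of mast cells and basophils, rose by 5.72 and the cytokine gene Il4 rose by 4.48. The eosinophil granule gene Prg2 fell by 6.67 and the basophil protease gene Mcpt8 fell by 5.67.

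Of the 15 measured panel genes (sort markers, fusion partners and regulators) 8 fell and 3 rose. Kit fell by 0.76 with the brighter of its probe sets (10.39 ± 0.04 to 9.64 ± 0.25 log2, SD, n = 3 each, limma adjusted p = 0.00436), and the other gave 0.72 (adjusted p = 0.199, limma). With the mean of both, Kit gave -0.02 (adjusted p = 0.945, limma). Cd34 fell by 3.60, Flt3, a receptor tyrosine kinase of early progenitors, fell by 3.95, and the transcription factor genes Cebpa and Sox4 fell by 5.39 and 4.03, while Jak1 and Jak2 rose by 0.59 and 0.71. Runx1, the mouse counterpart of the fusion's AML1 part, rose by 1.71 (limma adjusted p = 0.0266), and each of its 6 probe sets was higher. That call was lost without wild-type replicate 2 (adjusted p = 0.0823, limma), without wild-type replicate 3 (adjusted p = 0.0965), without leukemia replicate 3 (adjusted p = 0.0574) and with the fluidics run as a block (0.72, adjusted p = 0.210). Runx1t1, the counterpart of the ETO part, was left out of the test as dim, at 3.08 ± 0.20 log2 in wild-type and at 8.15, 8.27 and 4.79 on leukemia arrays 1, 2 and 3 (exact permutation p = 0.1, difference 2.73 with 16 added before the log). Its other probe sets, also left out as dim, were higher in leukemia by 3.93, 3.29, 2.34 and 0.42 log2. The mouse probe sets of Runx1t1 need not detect the transduced fusion.

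Spi1, a regulator of myeloid fate, fell by 0.64 (limma adjusted p = 0.0324), a call lost without wild-type replicate 2 (adjusted p = 0.110, limma), wild-type replicate 3 (0.104), leukemia replicate 2 (0.0521) or leukemia replicate 3 (0.0780), on centring of the arrays (0.0654) and with the block (0.156). Myc fell by 1.07 (limma adjusted p = 0.0369), lost without wild-type replicates 1, 2 or 3 (adjusted p = 0.0939, 0.0878 and 0.117) and without the intensity trend (0.0513), and was at -0.66 without leukemia replicate 1 and at -1.91 on that array alone. Gata1 (change 0.45, limma adjusted p = 0.108) and Gata2 (change -0.11, limma adjusted p = 0.776) did not pass. Gata2 was at 0.22 without leukemia replicate 1 and at -0.75 with the block, where it passed (adjusted p = 0.0128, limma) on the strength of that array alone. Fcgr3 (change 0.78, limma adjusted p = 0.318) passed only without leukemia replicate 3 among the arrays left out (1.41, adjusted p = 0.0329, limma). It was at 0.12 without leukemia replicate 1 and at 2.10 with the block, where it passed (adjusted p = 0.00915, limma), again on the strength of that array alone.

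**Figure D2:**
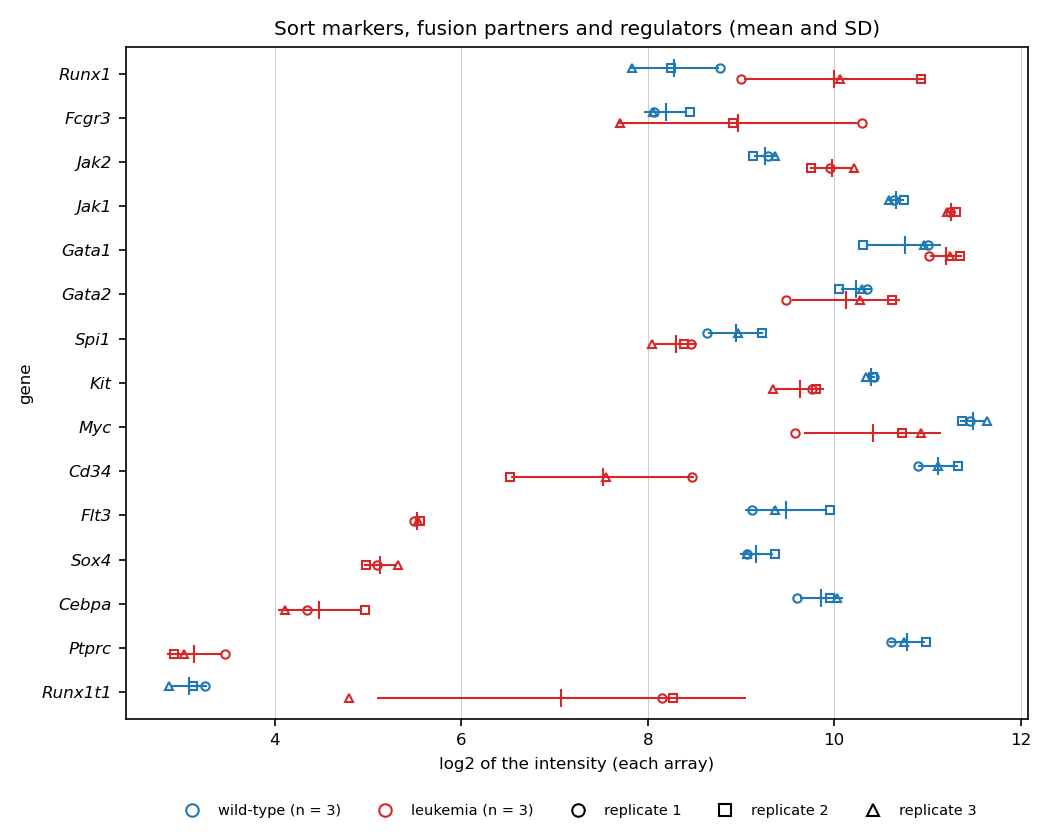
Log2 intensity (horizontal axis) of the 15 measured genes fixed as sort markers, fusion partners and regulators (vertical axis), blue for wild-type and red for leukemia arrays, marker shape for the replicate, and a vertical tick with a bar for the mean and SD of 3 arrays. Ptprc (change -7.64) and Cebpa (change -5.39) show no overlap, while Gata2 (change -0.11) overlaps between the groups and turns to 0.22 without leukemia replicate 1.

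Stem and primitive progenitor genes were lower. Of 22 tested 4 rose and 12 fell (13 fell adjusted over the list alone), with a median of -1.003 (camera adjusted p = 0.0264; adjusted p = 0.247 with an estimated correlation). Hoxa9, a homeobox gene of early progenitors, fell by 6.04 and Angpt1 fell by 4.77, whereas Ctnnal1 rose by 4.26. Mycn is counted among the risen by its brightest probe set (5.88), while another of its tested probe sets fell by 3.66. Of 17 genes described in human t(8;21) leukemia 3 rose and 10 fell, also adjusted over the list alone, with a median of -0.76 (camera adjusted p = 0.0132; adjusted p = 0.240 with an estimated correlation). Mpo and Ptprc fell most and Runx1 and Cdkn1a (1.33) rose most. With the fluidics run as a block neither list passed (median -1.05, camera adjusted p = 0.0960, and median -0.64, camera adjusted p = 0.0647), and the members of the leukemia list that no other list holds gave a camera adjusted p of 0.941. Without the filter on dim genes the medians were -0.35 for the stem list and -0.18 for the leukemia list, whose call was then lost (camera adjusted p = 0.224), and the stem call was lost with a stricter filter (median -0.41, camera adjusted p = 0.174) and with probe sets free of shared endings (0.0839).

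JAK/STAT, adhesion and interferon genes changed in opposing directions within each list. Of 33 JAK/STAT and cytokine receptor genes 10 rose and 17 fell (10 and 19 adjusted over the list alone), and the list did not pass (median -0.48, camera adjusted p = 0.202, median -0.44 with the block). Socs2, a feedback inhibitor induced by STAT5, rose by 5.01 and Csf2rb2, a cytokine receptor chain, rose by 3.08, while Ptprc fell by 7.64 and Csf3r, the receptor for G-CSF, fell by 4.50. Of 21 adhesion and homing genes 6 rose and 5 fell (8 and 5 adjusted over the list alone) and the list did not pass (camera adjusted p = 0.411, direction higher, median 0.09, mean -0.37, median -0.04 with the block). The chemokine receptor gene Cxcr4 fell by 5.34 and Selplg, the selectin ligand gene, fell by 2.86, whereas Adgre5 and the integrin gene Itgb1 rose by 2.26 and 1.44. Of 24 interferon response genes 2 rose and 6 fell, also adjusted over the list alone (median 0.28, camera adjusted p = 0.588), with Gbp3 falling most (fell by 2.59). The risen members were Oas1a (1.66, or 0.68 with the block) and Xaf1 (1.05). The call of Oas1a was lost without wild-type replicate 2 (adjusted p = 0.0522, limma) or 3 (0.0655), and that of Xaf1 with the mean of its probe sets (1.19, adjusted p = 0.0690). This list passed as higher without leukemia replicate 1 (camera adjusted p = 0.0197), and turned lower without leukemia replicate 3 (0.991) and with the block (median -0.39, 0.276).

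Mitosis genes were higher and ribosome biogenesis genes lower. Of 33 mitosis genes 18 rose and 0 fell (20 rose adjusted over the list alone), with a median of 0.45 (camera adjusted p = 2.64e-05; adjusted p = 0.291 with an estimated correlation; median 0.35 with the block), led by Kif23, a kinesin of cytokinesis (0.92). Of 34 ribosome biogenesis and MYC target genes 2 rose and 17 fell (20 fell adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.00506; adjusted p = 0.694 with an estimated correlation; median -0.59 with the block), led by Bop1 (fell by 1.17, -1.79 with the block). Of 36 DNA replication genes 2 rose and 12 fell, also adjusted over the list alone, without passing as a list (median -0.12, camera adjusted p = 0.173, median -0.19 with the block), and the helicase gene Mcm2 fell by 1.02. Of 34 DNA repair genes 5 rose and 7 fell, also adjusted over the list alone. That list did not pass (median -0.25, camera adjusted p = 0.683, median -0.35 with the block). The helicase gene Blm rose by 0.71, and Neil1 fell by 1.09, a call lost without wild-type replicate 3 (adjusted p = 0.0607, limma). Of 20 p53 target and apoptosis genes 8 rose and 4 fell, also adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.0132; adjusted p = 0.344 with an estimated correlation). Zmat3 and Phlda3 rose by 2.20 and 1.96, whereas Bcl2 fell by 3.13 and Bid fell by 1.88. The call of Bcl2 was lost without wild-type replicate 2 (adjusted p = 0.0512, limma), and its change was -2.78 with the block. The p53 list did not pass with the block (median 0.43, camera adjusted p = 0.0562).

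The joint list of immediate early and heat shock genes passed as higher, although its heat shock members Hspa1b and Hsph1 fell. Immediate early genes also respond to tissue handling. Of 17 immediate early and heat shock genes 10 rose and 3 fell, also adjusted over the list alone, with a median of 1.79 (camera adjusted p = 0.00594; adjusted p = 0.444 with an estimated correlation; median 2.27 with the block). The median was 1.14 without leukemia replicate 1 and 1.17 without the filter on dim genes. Klf6 rose by 2.84, while the heat shock genes Hspa1b and Hsph1 fell by 3.39 and 1.90 (Hsph1 -2.90 with the block). Metabolic lists did not pass. Of 52 oxidative phosphorylation genes 5 rose and 7 fell (0 and 2 adjusted over the list alone). Its median and mean were -0.01 and -0.003, while camera gave the direction as higher (adjusted p = 0.569), and lower without leukemia replicate 1 (0.960). The median was 0.04 with the block, and cytochrome c (Cycs) fell by 0.53. Of 18 glycolysis genes 5 rose and 5 fell, also adjusted over the list alone. The median of -0.20 and the mean of -0.11 again opposed camera's direction of higher (adjusted p = 0.714), and the median was -0.09 with the block. The glucose transporter gene Slc2a1 rose by 2.62 and Aldoc by 2.58, and the hexokinase gene Hk3 fell by 3.96.

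Markers of other cell types were mostly lower or mixed. Of 7 dendritic cell genes 1 rose and 3 fell, also adjusted over the list alone (median -0.23, camera adjusted p = 0.509, median -0.77 with the block), and Flt3, which is also a progenitor gene, fell by 3.95. Of 6 stromal and endothelial genes 4 fell, also adjusted over the list alone, with a median of -1.85 (camera adjusted p = 0.0415; adjusted p = 0.291 with an estimated correlation). Pecam1, an endothelial and leukocyte adhesion molecule, fell by 4.61 and Tie1 fell by 2.63. That call was lost without wild-type replicate 2 (camera adjusted p = 0.0752), without leukemia replicate 3 (0.0584) and with the block (median -1.64, 0.133), as well as without the filter on dim genes (median -0.03, 0.208). Of 5 T and NK cell genes 2 rose and 2 fell, also adjusted over the list alone (median 0.31, mean -0.60, camera direction higher, adjusted p = 0.745, median 0.20 with the block), among them Cd247 (rose by 1.36) and Il7r (fell by 3.13). Only 4 B cell genes could be tested, too few for a test of the list, of which Ighm fell by 4.69 and Cd72 fell by 1.52.

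**Figure D3:**
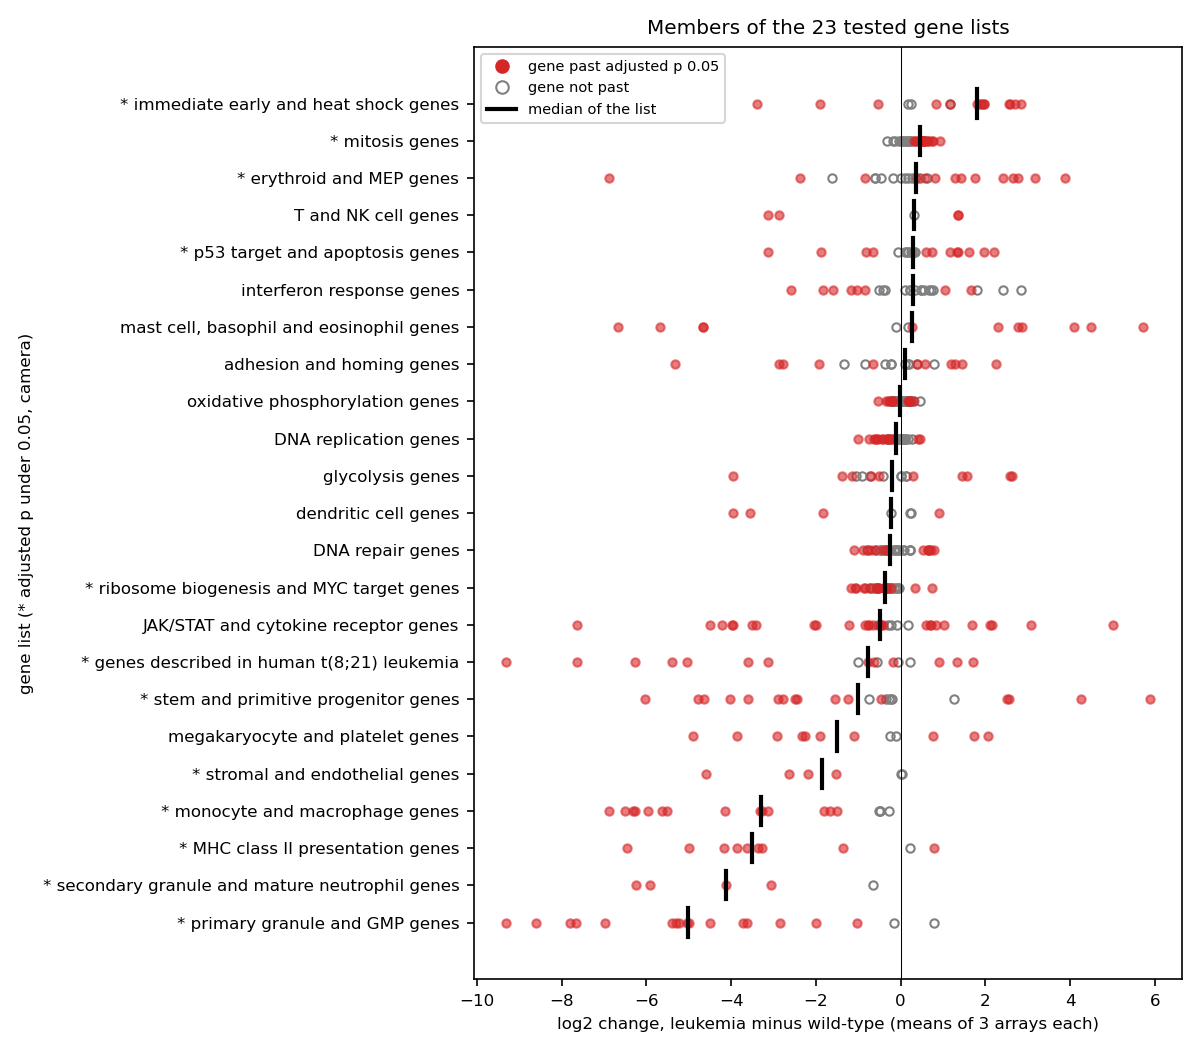
Log2 change in leukemia against wild-type (horizontal axis, means of 3 arrays each) of every tested member of the 23 tested gene lists (vertical axis), filled red where the gene passed and open grey where it did not, with a black line at the list's median and an asterisk where camera passed with its preset correlation. Medians run from -5.02 for primary granule and GMP genes to 1.79 for immediate early and heat shock genes, and no list passed with an estimated correlation.

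The size of some changes depended on the probe set. With the mean of all probe sets of a gene Ptprc was at -3.91, H2-Aa at -3.78, Hoxa9 at -3.56, H2-DMa at -2.94, Add2 at -1.27 and Mcm2 at -0.63. Socs2 was at 2.37, Jak1 at 1.36, Itgb1 at 0.86 and Mycn at 0.52. Except for Hoxa9, Add2, Mcm2 and Jak1, these means include probe sets too dim to be tested. The other Ptprc probe set lay at 3.18 log2 in wild-type and 3.00 in leukemia. The tested Socs2 probe sets rose by 5.01 and 5.58. With probe sets free of shared endings Colec11 was at 2.82 and Cycs at -0.32.

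Group and tissue cannot be told apart, since all leukemia cells were from spleen and all wild-type cells from bone marrow. By their hybridization date entries the arrays fell into 2 fluidics runs, of which only 1 held both groups (3 wild-type arrays and leukemia replicate 1). With the run as a block 5132 genes passed, 2028 higher and 3104 lower, 2436 of them at least 2-fold, a count that rests on leukemia replicate 1 alone.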

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

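The gene lists, the 3' minus 5' comparison of Gapdh and Actb and the fluidics run as a block had been planned, while their use to weigh explanations and the other tests in this part were chosen after the results were seen. Groups of 3 arrays were too small for a test of single outlying arrays, and the series holds 1 contrast.

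Lineage genes moved apart between the groups, with a median of -5.02 for primary granule and GMP genes and 0.37 for erythroid and MEP genes. Of the 26 erythroid and MEP genes 12 did not pass, and the call of that list was lost under several settings. A lower share of granulocyte-monocyte progenitors alone would raise the genes of the other progenitors alike. Of 26 erythroid and megakaryocyte genes well expressed in wild-type cells, however, 6 fell at least 2-fold (Aqp1, Cd9, Pf4, Add2, Itga2b and Gp9). Another 3 rose at least 2-fold (Ank1, Gp5 and Rhag) and 17 did neither. Aqp1 and Add2 are of the erythroid list, and the other fallen genes are of the megakaryocyte list. These falls argue against a lower share as the whole account only if both lineages kept their proportions. Of all 38 tested at any wild-type level, which adds risers dim in wild-type cells such as Alas2, 9 fell and 10 rose at least 2-fold. Normal basophils as most of the leukemia cells stay open. The 6 leukemia values of Mcpt8 and Ptprc, which basophils express, lay below the 40th percentile of all probe sets. The selection for Kit would also remove basophils that lack it. But Ptprc is among the 8 largest falls, Mcpt8 fell by 5.67, and both were chosen after these falls were seen. A further 3 genes that basophils express, Fcer1a, Ms4a2 and Hdc, rose by 2.29, 2.77 and 2.85. Normal mast cells, which express those 3 genes and Kit and could pass the sort, stay open too, as of the 6 leukemia values of Fcer1g and Ptprc, which such cells express, 5 lay below that percentile, while Fcer1g on the remaining array lay 0.06 above it. Tissue of origin and leukemia cannot be told apart, because the groups share 0 tissues, and a change of program in the leukemia cells may remain as a hypothesis beside these.

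The control probe sets for 18S ribosomal RNA, outside the gene comparison, were brighter on every leukemia array than on every wild-type array, 8.73-fold at the 5' end, 3.65-fold in the middle and 1.98-fold at the 3' end. Whether brightness of the whole hybridisation was the sole cause at the 5' end cannot be decided here. The values had been processed with RMA and array medians ran only from 71.6 to 79.9, so overall brightness may already have been evened out. The 5' shift exceeded that of the spiked bioB controls by 2.70 log2, against a standard error of 0.63 for the 5' shift alone. In the middle and at the 3' end the shifts were 1.87 and 0.98 log2, against 0.42 for bioB, and these were not tested. Degraded RNA stays open, because only 1 of 2 control genes, Gapdh but not Actb, had a higher 3' minus 5' difference on every leukemia array. The fluidics run stays open too: the change was 3.90 with the run as a block, but this rests on 1 leukemia array. No biological explanation was tested.

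Xist, left out of the gene test as dim, was higher in leukemia by 3.93 log2 on average (3.38 with 16 added before the log, since it was below the 40th percentile on all 3 wild-type arrays and on 1 leukemia array), with leukemia replicate 2 carrying both Xist and Y-linked transcripts. Progenitors like those of the wild-type sort are argued against as the source of the Y-linked signal of leukemia replicate 2. Mpo, Elane, Plac8 and Ptprc there reached at most 0.574% of the wild-type level, while each Y-linked gene reached at least 98.7%. These 4 genes are among the 8 largest falls, so they were known to be low there when chosen. A mixture of male and female cells in leukemia replicate 2 stays open, since its test depends on the reference. The female share was taken against leukemia replicate 1 (0.327). The shares summed to 0.994 where the male share was taken against leukemia replicate 3 (0.667) and to 1.54 where it was taken against the wild-type mean (1.21). Whether such cells would be donor and host cells of the transplantation or cells of several mice was not tested, nor was any biological explanation.

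Runx1t1, also left out as dim, was higher in leukemia by 3.995 log2 with its brightest probe set, or by 2.73 with 16 added before the log. That probe set was above every wild-type array on each leukemia array. It was below the 40th percentile on all 3 wild-type arrays and on leukemia replicate 3. Of 1771 tested probe sets without a single gene symbol, 263 changed at least 2-fold (limma, adjusted p under 0.05), 133 higher and 130 lower.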

How the results depend on the processing

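Of these tests, log2(value + 16) and fry were chosen after the results were seen. The 3 against 3 arrays make 10 splits, too few for a share under 0.05: 1 split, the real one, gave 4089 changed genes and 1849 at least 2-fold, and the highest of the others gave 0 and 0. The count of changed genes was 2377 at adjusted p under 0.01 and 2647 to 4716 when 1 array was left out, lowest without wild-type replicate 3 (fewer arrays; the cause was not tested further). Centring on array medians gave 3984 changed genes, 52.0% of them lower against 59.97%. The replicate numbers did not pair the arrays (r of same-numbered deviations -0.069, 0.050 and 0.030; not every array was closest to its own number), and the replicate block gave 3565 changed genes and 1856 at least 2-fold, with the stromal list at 0.0587. Values given for lists are adjusted p values of camera unless fry is named. With an estimated correlation the adjusted p of the 12 called lists was 0.240 for primary granule, monocyte, MHC class II and t(8;21) genes, 0.247 for secondary granule and stem genes, 0.291 for stromal and mitosis genes, 0.344 for p53, 0.444 for immediate early and 0.694 for erythroid and ribosome biogenesis genes. With the fluidics run as a block, which rests on leukemia replicate 1 alone, the erythroid (0.280), stromal (0.133), stem (0.0960), p53 (0.0562) and t(8;21) lists (0.0647) no longer passed and interferon genes turned lower (0.276). Leaving out 1 array gave ranges of 0.00447 to 0.0748 for erythroid, 0.0229 to 0.0752 for stromal, 0.0197 to 0.991 for interferon (past as higher without leukemia replicate 1, turned without leukemia replicate 3) and 0.281 to 0.960 for oxidative phosphorylation genes (turned without leukemia replicate 1). Without the filter on dim genes the stromal (0.208) and t(8;21) lists (0.224) did not pass and the T and NK list turned (0.198). Stromal genes were at 0.0664 on quantile normalization and 0.0521 on ranks. Stem genes were at 0.174 with the stricter filter and 0.0839 with probe sets free of shared endings, where MHC class II was at 0.112, and glycolysis (0.342) and DNA repair (0.923) turned. Glycolysis also turned with mean probe sets (0.971), and t(8;21) genes not in other lists gave 0.941. By fry, megakaryocyte (3.27e-04), dendritic (0.0159), DNA replication (0.0389) and JAK/STAT genes (0.00576) passed, erythroid (0.120) and ribosome biogenesis genes (0.0580) did not, and T and NK (0.0798), oxidative phosphorylation (0.789), glycolysis (0.789) and interferon genes (0.636) turned. Gata2 turned with array weights (0.11) and lay between -0.35 and 0.22 when 1 array was left out, highest without leukemia replicate 1. The cause of these changes was not tested. Robust moderation was not run for lists, since camera has no such option. Signal over background limits folds of genes dim in 1 group, as 16 added before the log shows for the 8 largest rises (4.52 to 6.75).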

Other observations

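Genes outside the fixed lists, chosen after their values were seen, are given as single genes, with no test of a group (limma, adjusted p over all genes tested). Pax6, known from eye and brain development, rose by 4.49 (limma adjusted p = 0.0130), with an SD of 2.34 log2 over the leukemia arrays. Meis2 rose by 4.31, Wt1 by 3.98, Gata3, a T cell and mast cell factor, by 3.69 and the Notch target Hes1 by 3.17. Mef2c, a factor of lymphoid and myeloid progenitors, fell by 6.40, Satb1 fell by 4.87 and Cebpd fell by 4.43. Alox5, the enzyme that begins leukotriene synthesis, rose by 3.98, Adora3 by 3.41, the histamine receptor gene Hrh4 by 2.85 and Cd200r1 by 2.76. The mast cell protease gene Mcpt2 rose by 3.70 (limma adjusted p = 0.0378), with an SD of 2.56 log2 over the leukemia arrays. Fcer1g, the signalling chain of the IgE receptor, fell by 4.50. The list of mast cell, basophil and eosinophil genes fixed beforehand did not pass (camera adjusted p = 0.197). Dntt and Cd27, known from lymphoid progenitors, fell by 5.52 and 5.17.

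Mycn was measured by a pair of tested probe sets that opposed each other, as one rose by 5.88 and the other fell by 3.66. Sox4 fell with each of its 4 tested probe sets, and with one of them fell by 8.32, against -4.03 with the one used.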
